A study of Mus musculus with 9 samples.

How the data were processed

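The data are 9 RNA-seq libraries of mouse ovary (C57BL/6, oocyte-specific knock-in of a PIK3CA transgene), 3 at each of postnatal day 8, day 50 and day 65. Per the labels, total RNA was isolated with a column kit and libraries were made with an mRNA kit. Groups were taken from the labelled age. No other genotype was part of the comparisons, and whether the libraries of an age came from separate animals is not given in the sources used here.

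Each library has 1 deposited table of 55487 rows, 1 per gene. Per the file headers, the authors estimated expected counts per gene with RSEM, which shares reads that map to several genes or transcripts between them, and the expected counts are not normalized. The authors also deposited TPM values, scaled by RSEM to effective length and to the sum over all genes. The deposited FPKM values were scaled by the authors to effective length and to mapped fragments. The deposited effective length, in bases, is the gene length corrected for fragment length. In 5090 single-transcript genes of 2 kb or more, its median distance below the annotated length was 74.14 to 74.32 bases per library. That correction therefore hardly differed between libraries. The genome build is GRCm38 (mm10) per the labels, and the aligner, the software versions and the strand setting of the counting are not given in the sources used here. No row lacked a gene name, 111 rows repeated the symbol of another row, and no 2 libraries were identical. Coordinates were given for 51114 rows and missing in 4373. In 41288 rows they equalled those of GENCODE M21, and GC content could be assigned to 55400 rows (99.8%). GENCODE M21 also supplied strand, biotype and exon overlap. FPKM and TPM were not used for tests.

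Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 17747 genes, and libraries were scaled with TMM factors. Total counts per library ran from 14116908 to 18868831. A count of 0 in each of the 3 libraries of an age allows a level of up to 0.0619 CPM at day 8, 0.0545 CPM at day 50 and 0.0671 CPM at day 65 (3 counts over the group). Folds against an age with 0 counts are given as bounds against that floor. For genes with 1 to 3 counts at an age, the ratio is given with an exact binomial 95% interval. Reads carry no molecular identifiers, so floors and intervals cover counting error only.

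Age is the only factor in the labels, so the 9 libraries entered 1 model with a term per age. Each pair of ages was compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, robust, two-sided). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 17747 genes of a comparison. Values per age are means and SD of TMM-normalized CPM. Genes called in the same direction at both consecutive steps were counted, and the counts were set beside the product expected for independent lists and beside simulated unchanged groups, since both steps share the day 50 libraries. The spread at each age was described by the biological coefficient of variation of edgeR's common dispersion.

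The comparisons, tests, 25 gene lists (370 members), rule for named genes and alternative settings were fixed before the data were examined. The cell type lists were granulosa cell, oocyte, Sertoli cell, theca and steroidogenesis, corpus luteum, stromal fibroblast, smooth muscle and pericyte, endothelial, macrophage and antigen presentation, lymphocyte, surface epithelium and mesothelium, oviduct epithelium, adipocyte and erythroid. The others were ovulation response, cell cycle, FOXO targets and PI3K feedback, cholesterol synthesis, glycolysis and hypoxia, WNT and beta-catenin targets, TGF-beta family signalling, matrix remodelling and mesenchymal transition, interferon response, immediate early and tissue handling, and mitochondrially encoded mRNA. Lists with at least 3 tested members were tested with camera (limma 3.58.1, competitive, two-sided, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, 1 way, and it does not compare the list with other genes.

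Genes were named by rule. In each comparison these were the 10 genes with the largest positive and the 10 with the largest negative log2 fold change, among called genes with a mean of at least 10 CPM over the 9 libraries and no overlap between the libraries of the compared ages. Predicted or clone-named genes, immunoglobulin and T cell receptor segments and pseudogenes were counted without being named. For each list up to 4 called members were eligible, those with the smallest p in the direction most called members took. Where members were called in the other direction, the 4 included the member with the smallest p in that direction. The text gives a selection of these, and some are not reported here. Pik3ca, Gdf9, Foxl2, Amh, Inha, Sox9 and Mki67 were reported whatever their values.

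The alternative settings were DESeq2 size factors, upper quartile factors, library size as the only scaling, and normalization without oocyte and mitochondrially encoded genes. Others were no filter on low counts, a stricter filter (5 CPM in 3 libraries), the Wald test of DESeq2 1.42.0, limma-voom, an offset for effective length, the 6 compared libraries alone, a fold change of at least 2, replicate number as a block, and leaving out each library. The trend of log-CPM on gene length and GC content (natural splines with 5 degrees of freedom each) was removed from each library through an offset, as an alternative added after seeing the data. Other groupings of the libraries were counted over the 10 splits of 6 libraries and over 60 drawn splits of the 9 libraries. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

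The procedure was tested on simulated data with the library sizes and dispersions of the 17747 genes, in 8 draws with 200 changed genes each, shared equally between 2-fold and 4-fold changes. At a 4-fold change it recovered 74.9% of changed genes between day 50 and day 8, 75.5% between day 65 and day 50 and 76% between day 65 and day 8. For genes at 10 CPM or more these values were 96.3%, 95.3% and 96.3%. At a 2-fold change it recovered 34.9%, 34.9% and 38.8% of all changed genes and 53.8%, 56.2% and 60.4% of those at 10 CPM or more. An earlier requirement of the self-test, that 80% of genes be recovered at 4-fold, was not met and was replaced after these values were seen by requirements on genes at 10 CPM or more, on fold change error and on false calls. False calls made up 4.22%, 6.03% and 7.00% of calls on average, against a nominal 5%. These rates belong to draws with few changed genes and 1 dispersion per gene for all ages, and need not hold for the real libraries. The list test, run on 1 draw per comparison, recovered the changed list in each, with 0, 1 and 0 false lists. Genes were drawn independently of each other, so the draws held no correlation between genes, on which the false calls of camera depend. These counts therefore do not give its rate of false lists in the real libraries. In a simulation with a length trend between day 65 and day 50, the test made 1321 false calls without the correction for length and GC content and 4 with it, while 160 and 151 of the 200 changed genes were recovered. The simulated trend was linear in log gene length, a form the correction can fit, so its removal was largely fixed in advance. The draw does not test the correction where real age changes go with gene length.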

Results

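Gene expression was measured by RNA-seq in 9 ovary libraries from C57BL/6 mice that carried an oocyte-specific knock-in of a PIK3CA transgene. The series describes the tissue as tumor samples collected over a time course. The libraries fall into 3 ages, postnatal day 8, day 50 and day 65, with 3 libraries at each age. Every library has the same genotype, so the comparisons are between ages, and ovaries of another genotype were not analysed here. The labels number the libraries within an age without saying that they came from separate animals, so p-values measure the spread between these libraries, which may be technical. That spread was pooled over the 3 ages, so the p-values of a pair of ages also depend on the libraries of the third. Total expected counts ran from 14116908 to 18868831 per library, and between 21305 and 26084 genes had a count above 0. Of 55487 rows, 17747 passed the filter on low counts and were tested. Levels are given as normalized CPM (counts scaled to the effective library size), as mean ± SD over n = 3 libraries, and coordinates are those of the files on GRCm38 (mm10).

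Libraries of 1 age resembled each other more than libraries of different ages. Spearman correlations of log2 CPM across genes were 0.962 to 0.992 within an age and 0.790 to 0.915 between ages, and the leading 2 principal components held 61.1% and 24.0% of the variance. The biological coefficient of variation was 27.4% at day 8, 12.0% at day 50 and 28.0% at day 65, and without day 8 replicate 1 the day 8 value was 12.6%. The mean effective length, weighted by TPM, was 1203 bases in day 8 replicate 1 and 1071 to 1195 bases in the day 65 libraries. In the other libraries it was 1564 to 1750 bases. Abundant short transcripts lower this mean, so it is not independent of the ribosomal protein share. Ribosomal protein genes took 10.9% of reads in day 8 replicate 1, 9.23% to 12.1% at day 65 and 2.90% to 5.50% in the other libraries. Mitochondrially encoded genes took 4.09% of reads in day 8 replicate 1, 4.46% to 5.04% at day 65 and 1.86% to 3.25% in the other libraries. CT010467.1, annotated as ribosomal RNA, took 3.82% to 7.91% of reads at day 8, 0.884% to 2.39% at day 50 and 0.451% to 1.04% at day 65. The overlapping gene AY036118, chosen after its values were seen, was at 0 in each day 8 and day 50 library and at 2089.7 ± 1019 CPM at day 65.

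**Figure D1:**
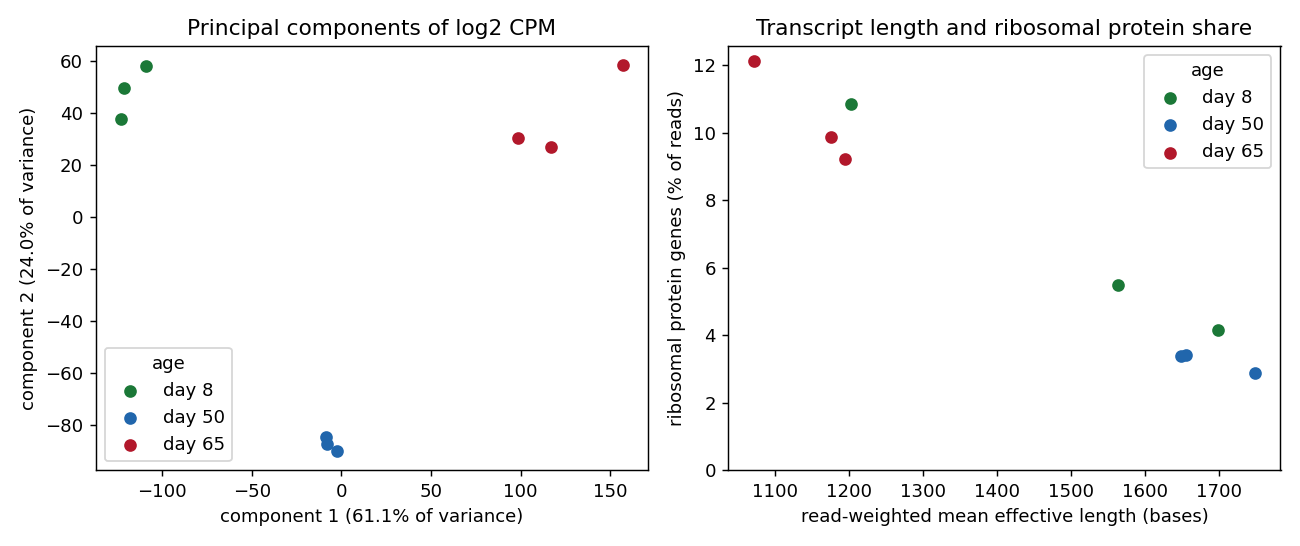
Left, each point is 1 library on the leading 2 principal components of log2 CPM, with 61.1% and 24.0% of the variance, coloured by age. Right, the mean effective length in bases, weighted by TPM (the axis label says read-weighted), against the percent of reads in ribosomal protein genes. Day 8 replicate 1 (1203 bases, 10.9%) lies with the day 65 libraries (1071 to 1195 bases).

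Pik3ca (chromosome 3, 32397671 to 32466107), which encodes a catalytic subunit of phosphoinositide 3-kinase and is the gene named by the genotype, was measured at 75.9 ± 17.4 CPM at day 8, 125 ± 10.8 CPM at day 50 and 72.9 ± 7.44 CPM at day 65. It was higher at day 50 than at day 8 by a log2 fold change of 0.72 (SE 0.173), with an edgeR adjusted p of 0.00755. It was lower at day 65 than at day 50 by a log2 fold change of -0.78 (SE 0.173), with an edgeR adjusted p of 0.00356. That call ended when each library's trend with gene length and GC content was removed (log2 fold change -0.09, edgeR adjusted p = 0.719), a setting chosen after seeing the data, in which day 65 exceeded day 8 by 0.62 (edgeR adjusted p = 0.0194) against -0.06 (edgeR adjusted p = 0.784) without it. The sources used here do not give whether transgene reads are counted in this row.

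Gdf9 (chromosome 11, 53431023 to 53437904), a growth factor secreted by oocytes, fell from 354 ± 52.4 to 30.1 ± 5.81 CPM between day 8 and day 50 (edgeR adjusted p = 1.99e-06) and stood at 42.7 ± 7.10 CPM at day 65. Foxl2 (chromosome 9, 98955607 to 98956847), a transcription factor of granulosa cells, rose from 154 ± 36.4 to 310.2 ± 9.59 CPM (edgeR adjusted p = 0.00188) and stood at 466 ± 67.2 CPM at day 65. For the step from day 50 to day 65, edgeR adjusted p was 0.0412 for Gdf9 and 0.0220 for Foxl2. The Gdf9 call at that step ended without day 8 replicate 3 (0.0599), day 50 replicate 2 (0.168) or 3 (0.0967), or day 65 replicate 1 (0.0810) or 3 (0.151), and under 3 other settings (0.0569 to 0.313). The Foxl2 call ended without day 50 replicate 1 (0.0549), 2 (0.0638) or 3 (0.0529), without day 65 replicate 1 (0.0730) or 3 (0.0543), and with library size as the only scaling (0.225). Inha (chromosome 1, 75507077 to 75510366), the inhibin alpha subunit, rose from 322 ± 168 to 3154 ± 411 CPM and then fell to 1175 ± 124 CPM (edgeR adjusted p = 5.71e-05 and 0.00423). Amh (chromosome 10, 80805248 to 80807648), a hormone of granulosa cells in growing follicles, measured 74.3 ± 32.7 CPM at day 8 and 96.98 ± 10.8 CPM at day 50 (edgeR adjusted p = 0.540) and fell to 13.7 ± 11.2 CPM at day 65 (edgeR adjusted p = 0.00121), a log2 fold change of -2.81 that was -3.75 without day 65 replicate 3. Sox9 (chromosome 11, 112782224 to 112787760), a Sertoli cell transcription factor, rose from 8.33 ± 1.67 to 22.4 ± 2.30 CPM and fell to 7.49 ± 3.35 CPM at day 65 (edgeR adjusted p = 0.00377 and 0.00165). Mki67 (chromosome 7, 135689784 to 135716361), a proliferation marker, measured 240.1 ± 33.3, 190.0 ± 29.2 and 337 ± 23.1 CPM at the 3 ages, and its rise from day 50 to day 65 passed the test (edgeR adjusted p = 0.00174). Its difference between day 65 and day 8 (edgeR adjusted p = 0.0219) did not pass without day 8 replicate 3 (0.0559), without day 65 replicate 3 (0.0697) or with library size as the only scaling (0.377).

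**Figure D2:**
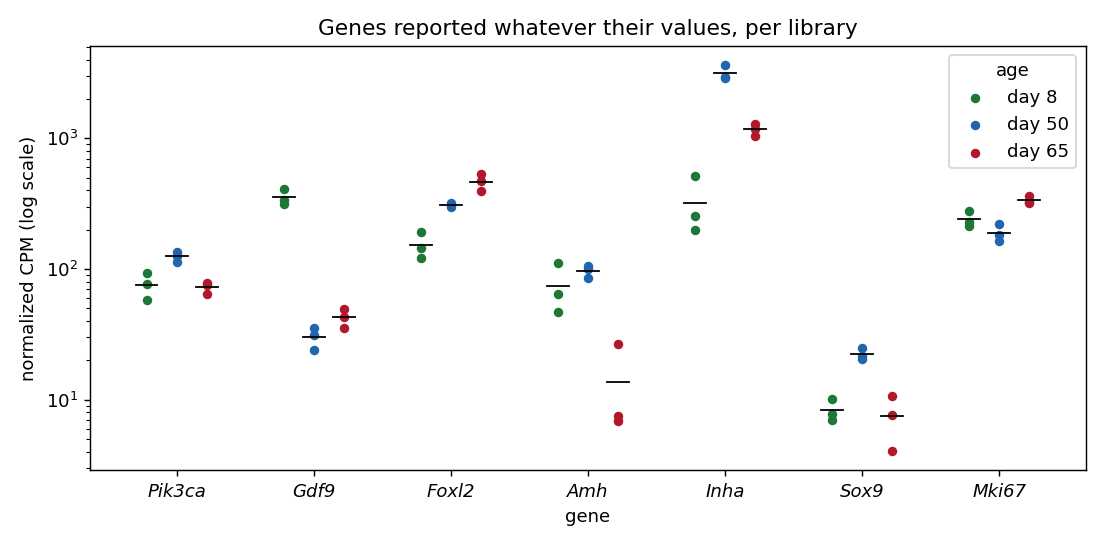
Normalized CPM on a log scale for 7 genes reported whatever their values, with 1 point per library coloured by age and a bar at the mean of 3 libraries. Gdf9 stands at 354 ± 52.4 CPM at day 8 and 30.1 ± 5.81 CPM at day 50, and Inha at 3154 ± 411 CPM at day 50 and 1175 ± 124 CPM at day 65.

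Day 50 was compared with day 8 to ask how the transcriptome of these ovaries differed between the first 2 ages. Of the oocyte list 23 of 25 tested genes fell and 0 rose, of the granulosa cell list 13 of 20 tested genes rose and 1 fell, and of the theca and steroidogenesis list 11 of 14 tested genes rose and 1 fell. Camera called these 3 lists at its preset correlation and not with an estimated correlation (adjusted p = 0.355 for each). Among the genes with the largest falls, Mov10l1 and Mael, which act in the piRNA pathway, went from 67.2 ± 18.7 to 0.0907 ± 0.0309 CPM and from 91.7 ± 13.1 to 0.396 ± 0.116 CPM. Of the synaptonemal complex genes, Sycp1 fell from 32.2 ± 2.19 to 0.0891 ± 0.0795 CPM and Sycp3 from 78.9 ± 18.6 to 0.110 ± 0.0583 CPM, the latter with 52.2% of its exon bases overlapped by Chpt1. Smc1b, a meiotic cohesin subunit, fell from 139 ± 30.2 to 0.479 ± 0.293 CPM, Tdrd9, a piRNA pathway helicase, from 54.5 ± 12.04 to 0.236 ± 0.117 CPM, and Trim71 from 85.8 ± 15.7 to 0.306 ± 0.0939 CPM. Among the largest rises, Edn1, the vasoconstrictor peptide endothelin 1, went from 1.30 ± 0.686 to 106 ± 11.97 CPM (81.8-fold), and Angpt2, a ligand of the endothelial receptor Tek, from 7.90 ± 3.69 to 488 ± 24.5 CPM (61.9-fold). Pln, phospholamban, rose 83.5-fold from 0.432 ± 0.205 to 35.5 ± 3.23 CPM, with 59.6% of its exon bases overlapped by Gm47644. Slc38a5, an amino acid transporter, rose from 22.9 ± 21.7 to 1192 ± 133 CPM, Serpina5, a serine protease inhibitor, from 1.04 ± 0.849 to 81.4 ± 19 CPM, and Dpp10 from 3.03 ± 1.18 to 137 ± 11.3 CPM. These genes had edgeR adjusted p from 2.52e-07 to 4.59e-04. Without 1 library the fitted fold moved by over 1.5 times for Slc38a5 (52.2-fold, and 103-fold without day 8 replicate 1) and Serpina5 (81.4-fold, and 122-fold without day 8 replicate 1).

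Of the lists of cell type markers, the oocyte list fell most: 23 of 25 tested members fell and 0 rose, with a median log2 fold change of -5.18 (camera adjusted p = 2.21e-10, and adjusted p = 0.355 with an estimated correlation). The germ cell helicase Ddx4 fell from 84.2 ± 11.6 to 1.10 ± 0.217 CPM, and the oocyte transcription factors Figla and Sohlh1 from 61.4 ± 10.7 to 0.125 ± 0.110 CPM and from 86.6 ± 15.8 to 0.220 ± 0.0633 CPM. In the granulosa cell list 13 of its 20 tested members rose and 1 fell (camera adjusted p = 6.15e-05, and adjusted p = 0.355 with an estimated correlation). The BMP antagonist Grem1 rose from 1.10 ± 0.721 to 70.2 ± 20.4 CPM, the gap junction gene Gja1 from 399 ± 131 to 6193 ± 495 CPM and the estradiol-synthesis gene Hsd17b1 from 50.03 ± 24.4 to 791 ± 49.7 CPM, while Gatm, an enzyme of creatine synthesis, fell from 297 ± 67.02 to 23.7 ± 3.76 CPM. In the theca and steroidogenesis list 11 of its 14 tested members rose and 1 fell (camera adjusted p = 6.15e-05, and adjusted p = 0.355 with an estimated correlation). Fdxr rose from 30.6 ± 3.66 to 197 ± 13.4 CPM and Srd5a1 from 8.17 ± 1.15 to 58.6 ± 6.46 CPM. The angiotensin receptor gene Agtr2 fell from 17.4 ± 6.66 to 2.57 ± 0.633 CPM. In the corpus luteum list, which shares Scarb1, Star, Lhcgr and Cyp11a1 with it, 6 of its 10 tested members rose and 1 fell (camera adjusted p = 0.0102, and adjusted p = 0.355 with an estimated correlation). The prolactin receptor gene Prlr rose from 9.16 ± 7.72 to 94.2 ± 14.8 CPM. In the macrophage and antigen presentation list 10 of its 15 tested members rose and 0 fell (camera adjusted p = 2.22e-04, and adjusted p = 0.438 with an estimated correlation). Cd68 rose from 3.56 ± 1.22 to 26.9 ± 5.85 CPM and Lyz2 from 35.2 ± 23.5 to 213 ± 32.96 CPM. In the smooth muscle and pericyte list 6 of its 11 tested members rose and 0 fell (camera adjusted p = 0.0328, and adjusted p = 0.560 with an estimated correlation). Mylk rose from 215 ± 35.01 to 931 ± 99.8 CPM and Acta2 from 282 ± 91.1 to 1328 ± 143 CPM. In the endothelial list 5 of its 13 tested members rose and 0 fell (camera adjusted p = 0.0328, and adjusted p = 0.459 with an estimated correlation). Pecam1 rose from 24.03 ± 2.20 to 44.8 ± 7.66 CPM and Cdh5 from 48.1 ± 6.46 to 87.6 ± 15.9 CPM. In the stromal fibroblast list 1 of its 15 tested members rose and 8 fell (camera adjusted p = 0.0200, and adjusted p = 0.438 with an estimated correlation). Mfap4 fell from 179 ± 17.9 to 30.3 ± 10.03 CPM and Tcf21 from 102 ± 15.9 to 34.99 ± 7.51 CPM. Fbln1 rose from 106 ± 5.41 to 319 ± 33.8 CPM. In the erythroid list 0 of its 6 tested members rose and 4 fell (camera adjusted p = 0.0485, and adjusted p = 0.490 with an estimated correlation). Hbb-bs fell from 890.1 ± 303 to 125 ± 37.8 CPM and Hbb-bt from 115 ± 69.2 to 15.3 ± 4.67 CPM. The fitted fold moved by over 1.5 times without 1 library for Figla (457-fold, and 304-fold without day 50 replicate 2), Prlr (10.4-fold, and 19.9-fold without day 8 replicate 1), Lyz2 (6.08-fold, and 9.71-fold without day 8 replicate 1) and Hbb-bt (7.52-fold, and 4.89-fold without day 8 replicate 3).

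Among the pathway lists, 13 of 18 tested members of the cholesterol synthesis list rose and 2 fell (camera adjusted p = 2.34e-04, and adjusted p = 0.355 with an estimated correlation). Msmo1 rose from 35.2 ± 11.1 to 145 ± 10.9 CPM. Insig1, a brake on the pathway, fell from 154 ± 14.6 to 79.2 ± 6.38 CPM. In the glycolysis and hypoxia list 12 of its 19 tested members rose and 1 fell (camera adjusted p = 4.22e-04, and adjusted p = 0.438 with an estimated correlation). Pfkp rose from 18.5 ± 2.72 to 109.7 ± 9.43 CPM and Hk2 from 12.5 ± 2.37 to 59.1 ± 5.47 CPM. In the list of FOXO targets and PI3K feedback 8 of its 17 tested members rose and 3 fell (camera adjusted p = 0.0328, and adjusted p = 0.384 with an estimated correlation). Foxo1, a transcription factor that AKT keeps out of the nucleus, rose from 88.3 ± 26.2 to 1010.0 ± 85.8 CPM (11.4-fold), and Cdkn1b, a cyclin-dependent kinase inhibitor, fell from 218 ± 14.9 to 100.4 ± 2.08 CPM. In the TGF-beta family signalling list 9 of its 24 tested members rose and 2 fell (camera adjusted p = 0.0242, and adjusted p = 0.384 with an estimated correlation). Bmp2 rose from 6.33 ± 0.816 to 96.7 ± 17.4 CPM and Bmpr1b from 33.99 ± 3.28 to 183 ± 11.4 CPM. Bmp7 fell from 18.1 ± 3.28 to 6.67 ± 0.538 CPM. In the interferon response list 7 of its 11 tested members rose and 0 fell (camera adjusted p = 0.00419, and adjusted p = 0.355 with an estimated correlation). Usp18 rose from 1.39 ± 0.204 to 16.5 ± 3.43 CPM. In the immediate early and tissue handling list 7 of its 13 tested members rose and 0 fell (camera adjusted p = 0.0186, and adjusted p = 0.464 with an estimated correlation). Junb rose from 9.44 ± 3.07 to 27.7 ± 2.04 CPM and Nr4a1 from 17.6 ± 8.10 to 83.8 ± 6.05 CPM. In the cell cycle list 0 of its 24 tested members rose and 9 fell (camera adjusted p = 0.0344, and adjusted p = 0.384 with an estimated correlation). Birc5 fell from 112 ± 6.27 to 27.2 ± 0.446 CPM and E2f1 from 47.7 ± 6.14 to 19.9 ± 1.70 CPM.

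The remaining lists gave no call. The Sertoli cell list had 6 members higher and 4 lower of 13 (camera adjusted p = 0.236). The ovulation response list had 0 members higher and 2 lower of 10 (camera adjusted p = 0.749). The lymphocyte list had 1 member higher and 0 lower of 5 (camera adjusted p = 0.237). The surface epithelium and mesothelium list had 0 members higher and 1 lower of 12 (camera adjusted p = 0.844). The oviduct epithelium list had 0 members higher and 1 lower of 6 (camera adjusted p = 0.438). The adipocyte list had 3 members higher and 0 lower of 5 (camera adjusted p = 0.0701). The WNT and beta-catenin targets list had 0 members higher and 3 lower of 10 (camera adjusted p = 0.174). The matrix remodelling and mesenchymal transition list had 7 members higher and 4 lower of 17 (camera adjusted p = 0.549). The mitochondrially encoded mRNA list had 0 members higher and 0 lower of 13 (camera adjusted p = 0.286). The matrix remodelling list had a median log2 fold change of -0.04 and a mean of 0.12. Adjusted over the list alone, passing members differed from the counts over all genes in oocyte (0 higher and 24 lower), Sertoli cell (6 higher and 5 lower), ovulation response (0 higher and 1 lower), stromal fibroblast (1 higher and 10 lower), adipocyte (4 higher and 0 lower), erythroid (0 higher and 5 lower), cell cycle (1 higher and 9 lower), cholesterol synthesis (14 higher and 2 lower), glycolysis and hypoxia (13 higher and 1 lower), TGF-beta family signalling (12 higher and 3 lower) and interferon response (8 higher and 0 lower).

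In all, 7249 of 17747 genes differed between day 50 and day 8 by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, 3455 of them higher and 3794 lower at day 50. Of the 16 lists called, none passed with an estimated correlation. There, 3 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.355. The fry test called 17. The ribosomal RNA share of reads also differed between these ages (3.82% to 7.91% at day 8 and 0.884% to 2.39% at day 50). With the trend on length and GC content removed, 6 lists missed the threshold with medians of the same sign. The smooth muscle and pericyte list had a median log2 fold change of 1.08 (quartiles 0.38 to 1.88) before and 1.06 (0.28 to 1.71) after (camera adjusted p = 0.0593). The endothelial list had a median log2 fold change of 0.39 (quartiles 0.16 to 0.87) before and 0.32 (0.13 to 0.77) after (camera adjusted p = 0.0683). The erythroid list had a median log2 fold change of -2.27 (quartiles -2.89 to -1.40) before and -1.996 (-2.56 to -1.26) after (camera adjusted p = 0.107). The FOXO targets and PI3K feedback list had a median log2 fold change of 0.46 (quartiles 0.06 to 0.90) before and 0.47 (-0.08 to 0.98) after (camera adjusted p = 0.0648). The TGF-beta family signalling list had a median log2 fold change of 0.32 (quartiles -0.33 to 1.11) before and 0.23 (-0.31 to 1.12) after (camera adjusted p = 0.0591). The immediate early and tissue handling list had a median log2 fold change of 0.84 (quartiles 0.41 to 1.56) before and 0.71 (0.23 to 1.42) after (camera adjusted p = 0.0594). Their mean test statistics came closer to 0 and the SD of the statistic over all genes was 2.52 in place of 2.42. A change of the list's own p alone would have ended 4 of these calls. The smooth muscle and TGF-beta calls (adjusted p = 0.0485 and 0.0473 with their own p changed alone) ended only together with the p of other lists, through the adjustment. The erythroid list also missed it with DESeq2's size factors (0.0536) and with library size as the only scaling (0.0519), and fry did not call the smooth muscle and pericyte list (0.0717). The cell cycle median of -0.23 was -0.14 without day 8 replicate 2, -0.15 without day 8 replicate 3 and -0.14 without day 50 replicate 1. The erythroid median was -0.84 without day 8 replicate 3, and the TGF-beta median 0.21 without day 8 replicate 1 and 0.53 without day 8 replicate 2. Camera calls also ended when single libraries were left out, with the adjusted p given in parentheses. The smooth muscle and pericyte call ended without day 8 replicate 2 (0.103), day 8 replicate 3 (0.0600), day 50 replicate 1 (0.0653) or day 50 replicate 3 (0.0807). The endothelial call ended without day 8 replicate 3 (0.0608) or day 50 replicate 1 (0.0656). The erythroid call ended without day 8 replicate 3 (0.107), day 50 replicate 1 (0.0899), day 65 replicate 2 (0.0563) or day 65 replicate 3 (0.0580). The cell cycle call ended without day 8 replicate 2 (0.0607), day 8 replicate 3 (0.0845), day 50 replicate 1 (0.108), day 50 replicate 2 (0.0785), day 50 replicate 3 (0.0558), day 65 replicate 2 (0.0533) or day 65 replicate 3 (0.0580). The TGF-beta family signalling call ended without day 8 replicate 1 (0.0507).

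**Figure D3:**
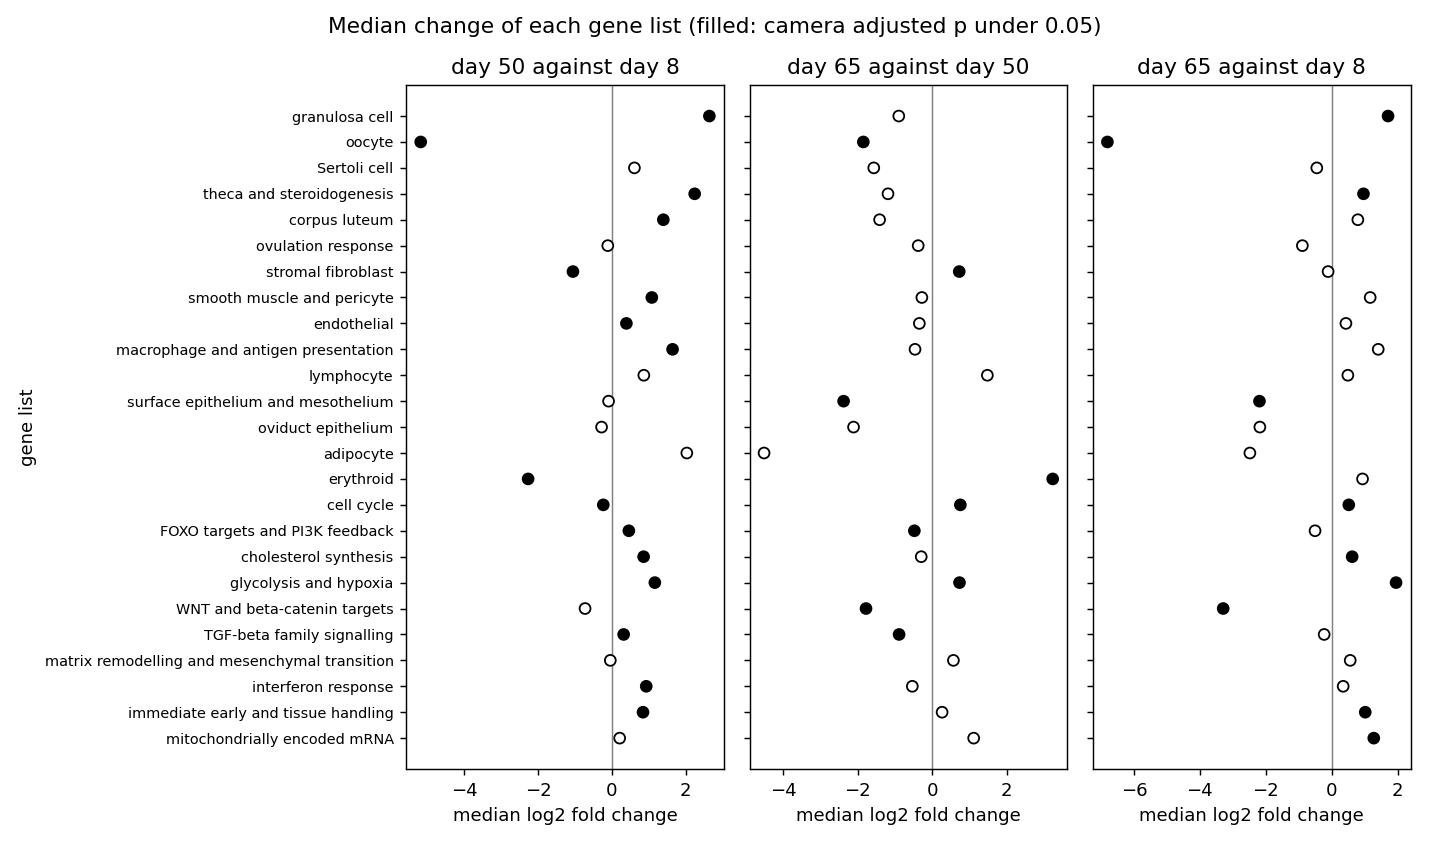
Median log2 fold change of the tested members of each of 25 gene lists (rows) in the 3 comparisons between ages (panels), with filled points for lists at a camera adjusted p under 0.05 at the preset correlation. The oocyte list lies at -5.18 between day 8 and day 50 and the cell cycle list at 0.76 between day 50 and day 65, and no list passed with an estimated correlation.

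Day 65 was compared with day 50 to ask how the last 2 ages differed. Of the cell cycle list 18 of 24 tested genes rose and 0 fell, of the WNT list 8 of 10 tested genes fell and 0 rose, and of the surface epithelium list 10 of 12 tested genes fell and 0 rose. These 3 lists were called by camera at its preset correlation and not with an estimated correlation (adjusted p = 0.170, 0.667 and 0.667 in that order). Retnla and Chil3, secreted proteins of alternatively activated macrophages, rose from 1.56 ± 2.27 to 155 ± 99.8 CPM and from 1.12 ± 1.60 to 69.4 ± 55.7 CPM. The macrophage and antigen presentation list, which holds neither gene, had 0 members higher and 4 lower of 15 at this step. Ctrb1, chymotrypsinogen, rose from 3.32 ± 2.27 to 189 ± 95.8 CPM, and Cdkn2a, which encodes cell cycle inhibitors, from 0.924 ± 0.127 to 30.7 ± 17.02 CPM (32.8-fold). Usp50 rose from 0.740 ± 0.432 to 109 ± 49.5 CPM (148-fold), the bradykinin receptor gene Bdkrb2 from 0.388 ± 0.287 to 55.5 ± 35.4 CPM, and the transcription factor gene Onecut2 from 1.04 ± 1.23 to 56.5 ± 12.9 CPM. In the other direction, Npr3, the clearance receptor of natriuretic peptides, fell from 143 ± 11.1 to 2.58 ± 0.815 CPM (54.4-fold), Dpp10 from 137 ± 11.3 to 2.45 ± 1.14 CPM (55.9-fold) and the catenin gene Ctnna2 from 61.6 ± 14.2 to 1.44 ± 1.53 CPM. The signalling ligand gene Wnt2b fell from 81.6 ± 2.90 to 2.42 ± 2.35 CPM, Dgkb, a diacylglycerol kinase, from 47.7 ± 4.38 to 1.21 ± 0.446 CPM, and Ankrd63 from 93.95 ± 18.6 to 1.02 ± 1.03 CPM. Galnt2, a glycosyltransferase gene, fell from 93.3 ± 12.3 to 1.90 ± 0.582 CPM, with 90% of its exon bases overlapped by Gm20388. These genes had edgeR adjusted p from 5.53e-06 to 9.76e-04. Leaving out 1 library moved the fitted fold by over 1.5 times for Retnla (95.9-fold, and 590.3-fold without day 50 replicate 3), Chil3 (59.8-fold, and 336-fold without day 50 replicate 3 and 33.3-fold without day 65 replicate 1), Ctrb1 (56.2-fold, and 91.2-fold without day 50 replicate 3), Bdkrb2 (137-fold, and 236-fold without day 50 replicate 3 and 87.3-fold without day 65 replicate 1) and Onecut2 (52.6-fold, and 163-fold without day 50 replicate 3). Among the falls it did so for Ctnna2 (39.9-fold, and 99.4-fold without day 65 replicate 3), Wnt2b (32.2-fold, and 74.6-fold without day 65 replicate 3) and Ankrd63 (84.9-fold, and 184-fold without day 65 replicate 3).

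The cell cycle list rose: 18 of 24 members were higher and 0 lower at day 65 (camera adjusted p = 5.59e-06, and adjusted p = 0.170 with an estimated correlation). Birc5, survivin, went from 27.2 ± 0.446 to 107 ± 9.27 CPM (3.93-fold), the mitotic kinase genes Aurka and Cdk1 from 27.5 ± 1.41 to 63.1 ± 3.74 CPM and from 53.5 ± 4.25 to 143 ± 2.70 CPM, and the cyclin gene Ccna2 from 90.6 ± 4.62 to 181 ± 7.48 CPM. In the list of WNT and beta-catenin targets 0 of its 10 tested members rose and 8 fell (camera adjusted p = 0.00901, and adjusted p = 0.667 with an estimated correlation). Axin2 fell from 37.6 ± 2.91 to 3.94 ± 1.48 CPM (9.37-fold) and Lgr5 from 56.7 ± 6.45 to 2.90 ± 2.74 CPM (18.7-fold, and 40.4-fold without day 65 replicate 3). In the surface epithelium and mesothelium list 0 of its 12 tested members rose and 10 fell (camera adjusted p = 0.00901, and adjusted p = 0.667 with an estimated correlation). Of the genes of mucin 16, mesothelin and E-cadherin, Muc16 fell from 34.8 ± 4.91 to 5.02 ± 3.76 CPM, Msln from 40.8 ± 8.75 to 8.28 ± 5.06 CPM and Cdh1 from 38.2 ± 4.84 to 5.07 ± 3.69 CPM. In the TGF-beta family signalling list 2 of its 24 tested members rose and 13 fell (camera adjusted p = 0.00927, and adjusted p = 0.646 with an estimated correlation). Bmp2 fell from 96.7 ± 17.4 to 7.31 ± 1.84 CPM, Tgfbr1 from 120.0 ± 9.85 to 38.5 ± 3.47 CPM and Id2 from 145 ± 9.23 to 18.7 ± 11.01 CPM. Bmp7 rose from 6.67 ± 0.538 to 15.5 ± 4.70 CPM. In the list of FOXO targets and PI3K feedback 1 of its 17 tested members rose and 10 fell (camera adjusted p = 0.0128, and adjusted p = 0.646 with an estimated correlation). Sesn3 fell from 191 ± 20.98 to 49.4 ± 8.91 CPM, Pik3ip1 from 54 ± 3.85 to 17.3 ± 2.77 CPM and Bcl6 from 22.5 ± 1.31 to 6.57 ± 0.732 CPM. Gadd45a of that list rose from 28.3 ± 3.95 to 53.8 ± 5.83 CPM, a rise that turned to a log2 fold change of -0.11 (edgeR adjusted p = 0.716) with the length and GC trend removed. In the glycolysis and hypoxia list 14 of its 19 tested members rose and 2 fell (camera adjusted p = 0.0211, and adjusted p = 0.667 with an estimated correlation). Egln3 rose from 9.21 ± 0.695 to 103 ± 63.5 CPM and Gapdh from 828 ± 69.2 to 1839 ± 634 CPM. Car9 fell from 40.9 ± 8.51 to 9.19 ± 5.75 CPM. In the stromal fibroblast list 9 of its 15 tested members rose and 1 fell (camera adjusted p = 0.0210, and adjusted p = 0.667 with an estimated correlation). Col1a1 rose from 245 ± 107 to 1588 ± 256 CPM, Mgp from 105 ± 23.97 to 595 ± 106 CPM and Mfap4 from 30.3 ± 10.03 to 178 ± 15.01 CPM. Ogn fell from 183 ± 17.8 to 49.8 ± 30.8 CPM. In the erythroid list 5 of its 6 tested members rose and 0 fell (camera adjusted p = 0.0128, and adjusted p = 0.667 with an estimated correlation). The globin gene Hba-a1 rose from 38.1 ± 9.03 to 994 ± 346 CPM and Hbb-bs from 125 ± 37.8 to 1218 ± 628 CPM. In the oocyte list 3 of its 25 tested members rose and 9 fell (camera adjusted p = 0.0291, and adjusted p = 0.667 with an estimated correlation). Ooep fell from 22.4 ± 5.61 to 7.39 ± 3.84 CPM and Zp1 from 7.72 ± 2.08 to 1.07 ± 1.66 CPM. Dazl rose from 3.66 ± 1.25 to 15.2 ± 3.38 CPM. Without day 65 replicate 3 the list's median log2 fold change of -1.85 was -4.80. Zp1, at a log2 fold change of -2.71, then had 3 counts against 427, a ratio of 70.7 with an exact binomial 95% counting interval of 24.03 to 344. Oog1 had 1 count at day 65 against 224 at day 50, a ratio of 182 with an exact binomial 95% counting interval of 32.3 to 7221, and without day 65 replicate 1 it had 0 counts at day 65, at least 44.3-fold lower against a floor of 3 counts over the remaining libraries. Single libraries also moved the fitted fold by over 1.5 times for Muc16 (6.74-fold, and 11.4-fold without day 65 replicate 3), Cdh1 (7.48-fold, and 12.02-fold without day 65 replicate 3), Egln3 (11.1-fold, and 7.37-fold without day 65 replicate 1) and Car9 (4.39-fold, and 6.84-fold without day 65 replicate 3).

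The other lists gave no call. The granulosa cell list had 4 members higher and 10 lower of 20 (camera adjusted p = 0.174). The Sertoli cell list had 2 members higher and 7 lower of 13 (camera adjusted p = 0.141). The theca and steroidogenesis list had 1 member higher and 8 lower of 14 (camera adjusted p = 0.158). The corpus luteum list had 2 members higher and 6 lower of 10 (camera adjusted p = 0.246). Within the granulosa cell list, the follicle-stimulating hormone receptor gene Fshr fell from 24.8 ± 4.04 to 0.656 ± 0.474 CPM (36.1-fold) and Slc18a2, a monoamine transporter, rose from 99.4 ± 23.7 to 697 ± 137 CPM, and within the theca list Cyp17a1, an enzyme of androgen synthesis, fell from 113 ± 65.7 to 7.95 ± 3.51 CPM. The ovulation response list had 3 members higher and 4 lower of 10 (camera adjusted p = 0.701). The smooth muscle and pericyte list had 1 member higher and 2 lower of 11 (camera adjusted p = 0.701). The endothelial list had 4 members higher and 3 lower of 13 (camera adjusted p = 0.640). The macrophage and antigen presentation list had 0 members higher and 4 lower of 15 (camera adjusted p = 0.174). The lymphocyte list had 2 members higher and 1 lower of 5 (camera adjusted p = 0.576). The oviduct epithelium list had 0 members higher and 4 lower of 6 (camera adjusted p = 0.141). The adipocyte list had 0 members higher and 3 lower of 5 (camera adjusted p = 0.174). The cholesterol synthesis list had 4 members higher and 8 lower of 18 (camera adjusted p = 0.603). Within the macrophage list, Lyz2 fell from 213 ± 32.96 to 39.2 ± 8.15 CPM. Within the adipocyte list, Cfd, at 16.1 ± 18.1 CPM at day 50, was at 0 in the day 65 libraries, at least 239.7-fold lower against a floor of 3 counts over the group. The bound was 89.3-fold without day 50 replicate 1, and 158-fold and 147-fold without day 65 replicate 2 or 3 in that order, which raises the floor. With genes at their bounds the list's median log2 fold change was -4.51, the same as without bounds. The matrix remodelling and mesenchymal transition list had 9 members higher and 3 lower of 17 (camera adjusted p = 0.141). The interferon response list had 2 members higher and 5 lower of 11 (camera adjusted p = 0.575). The immediate early and tissue handling list had 4 members higher and 2 lower of 13 (camera adjusted p = 0.657). The mitochondrially encoded mRNA list had 7 members higher and 0 lower of 13 (camera adjusted p = 0.0804). Within the interferon list Bst2, tetherin, rose from 94.04 ± 6.60 to 743 ± 217 CPM. Adjusted over the list alone, passing members differed from the counts over all genes in oocyte (2 higher and 8 lower), stromal fibroblast (10 higher and 1 lower), macrophage and antigen presentation (0 higher and 2 lower), surface epithelium and mesothelium (0 higher and 11 lower) and FOXO targets and PI3K feedback (1 higher and 11 lower).

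By edgeR's quasi-likelihood test 9916 of 17747 genes differed between day 65 and day 50, 4883 higher and 5033 lower at day 65. With library size as the only scaling, the share of higher genes was 35.5% in place of 49.2%, and the median of all genes moved by -0.26 on the log2 scale. Log2 fold changes fell with gene length (Spearman rho -0.401 across genes, which are not independent replicates). With the trend on length and GC content removed 8902 genes passed, with 6723 of the 9916 called in the same direction. Of the 9 lists called, none passed with an estimated correlation. There, 1 list had an unadjusted p under 0.05 and the smallest adjusted p was 0.170. The fry test called 15. With the length and GC trend removed, 2 lists missed the threshold, with medians of the same sign, because their mean test statistics came closer to 0. The FOXO targets and PI3K feedback list had a median log2 fold change of -0.48 (quartiles -1.64 to -0.36) before and -0.39 (-1.17 to 0.03) after (camera adjusted p = 0.0970). The TGF-beta family signalling list had a median log2 fold change of -0.89 (quartiles -1.44 to -0.13) before and -0.65 (-1.03 to 0.31) after (camera adjusted p = 0.0582). Camera calls also ended when single libraries were left out, with the adjusted p in parentheses. The oocyte call ended without day 50 replicate 3 (0.0505) or day 65 replicate 2 (0.147). The stromal fibroblast call ended without day 65 replicate 2 (0.0522). The glycolysis and hypoxia call ended without day 65 replicate 2 (0.0522). The oocyte list was also not called by fry (0.0794) or with library size as the only scaling (0.0602).

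**Figure D4:**
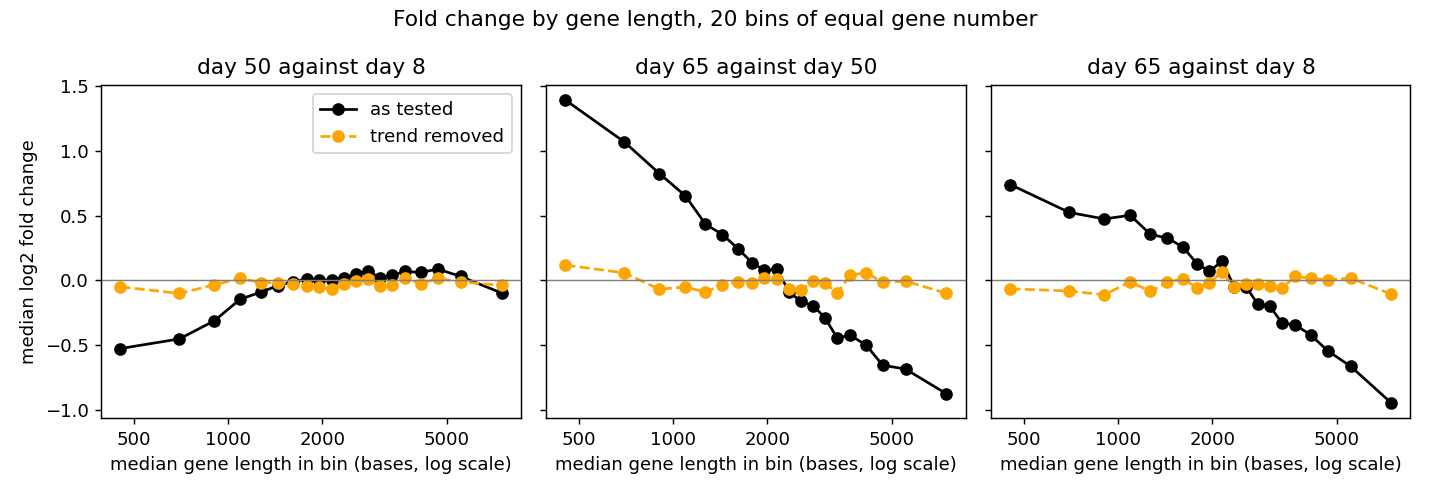
Median log2 fold change in 20 bins of genes ordered by length (bases, log scale) in each comparison, as tested (black) and with all libraries's trend on length and GC content removed (orange). Between day 65 and day 50 the black medians fall from 1.39 in the shortest bin to -0.88 in the longest.

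Day 65 was compared with day 8 to span the whole time course. Of the oocyte list 25 of 25 tested genes fell and 0 rose, of the glycolysis and hypoxia list 16 of 19 tested genes rose and 2 fell, and of the granulosa cell list 13 of 20 tested genes rose and 5 fell. Each of these 3 lists was called by camera at its preset correlation and not with an estimated correlation (adjusted p = 0.655 for each). Mov10l1, at 67.2 ± 18.7 CPM at day 8, was at 0 in the day 65 libraries, at least 1002-fold lower against a floor of 3 counts over the group, and Sycp1 at least 480.5-fold lower. Without day 65 replicate 2 or 3, which raises the floor, and in that order, the bounds were 659-fold and 612-fold for Mov10l1 and 316-fold and 294-fold for Sycp1. Trim71 had 2 counts at day 65 against 4229 at day 8, a ratio of 1953 with an exact binomial 95% counting interval of 540.2 to 16129. Padi6, a component of the oocyte cytoplasmic lattices, fell from 2215 ± 483 to 5.75 ± 7.98 CPM (375-fold, and 1853-fold without day 65 replicate 3). Among the rises, Retnla went from 0.0936 ± 0.115 to 155 ± 99.8 CPM and Ctrb1 from 0.309 ± 0.0356 to 189 ± 95.8 CPM (596-fold). Shisal2a rose from 0.145 ± 0.0312 to 55.7 ± 23.7 CPM, the GABA transporter gene Slc6a11 from 0.108 ± 0.0941 to 27.1 ± 4.16 CPM, the prohormone convertase gene Pcsk2 from 0.445 ± 0.328 to 86.1 ± 40.6 CPM and Sez6 from 0.316 ± 0.129 to 49.4 ± 11.6 CPM. These genes with a count at both ages had edgeR adjusted p from 1.80e-07 to 6.73e-05. Without day 8 replicate 1 Retnla had 1 count against 6612, a ratio of 5167 with an exact binomial 95% counting interval of 927 to 204110.0, and without day 8 replicate 2 Slc6a11 had 2 counts against 1191, a ratio of 416 with an exact binomial 95% counting interval of 115 to 3440.2, against fitted folds of 1712 and 244 with all libraries.

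In the oocyte list 0 of its 25 tested members rose and 25 fell (camera adjusted p = 2.90e-09, and adjusted p = 0.655 with an estimated correlation). Ddx4 fell from 84.2 ± 11.6 to 0.730 ± 0.165 CPM and Sohlh1 from 86.6 ± 15.8 to 0.123 ± 0.148 CPM. In the granulosa cell list 13 of its 20 tested members rose and 5 fell (camera adjusted p = 0.0143, and adjusted p = 0.655 with an estimated correlation). Grem1 rose from 1.10 ± 0.721 to 125 ± 21.5 CPM (116-fold) and the inhibin beta-B subunit gene Inhbb from 155 ± 69.1 to 2846 ± 332 CPM. Gatm fell from 297 ± 67.02 to 8.83 ± 3.61 CPM. In the theca and steroidogenesis list 9 of its 14 tested members rose and 2 fell (camera adjusted p = 0.0377, and adjusted p = 0.655 with an estimated correlation). Fdxr rose from 30.6 ± 3.66 to 203 ± 31 CPM and Scarb1 from 106 ± 4.70 to 657 ± 114 CPM. In the glycolysis and hypoxia list 16 of its 19 tested members rose and 2 fell (camera adjusted p = 2.14e-04, and adjusted p = 0.655 with an estimated correlation). Pfkp rose from 18.5 ± 2.72 to 163 ± 28.2 CPM and Ldha from 179 ± 27.3 to 862 ± 176 CPM. In the cholesterol synthesis list 11 of its 18 tested members rose and 1 fell (camera adjusted p = 0.00585, and adjusted p = 0.655 with an estimated correlation). Mvk rose from 11.4 ± 0.551 to 55.5 ± 15.2 CPM and Msmo1 from 35.2 ± 11.1 to 153 ± 25.2 CPM. In the cell cycle list 13 of its 24 tested members rose and 2 fell (camera adjusted p = 0.0184, and adjusted p = 0.655 with an estimated correlation). Ccnb2 rose from 51 ± 3.98 to 101 ± 5.25 CPM and Plk1 from 44.8 ± 6.88 to 121 ± 23.3 CPM. Mcm5 fell from 111 ± 6.76 to 76.2 ± 6.72 CPM. In the list of WNT and beta-catenin targets 0 of its 10 tested members rose and 8 fell (camera adjusted p = 0.00524, and adjusted p = 0.655 with an estimated correlation). Axin2 fell from 95.9 ± 23 to 3.94 ± 1.48 CPM (23.9-fold) and Nkd1 from 117 ± 22.98 to 19.5 ± 6.34 CPM. In the surface epithelium and mesothelium list 0 of its 12 tested members rose and 10 fell (camera adjusted p = 0.0144, and adjusted p = 0.691 with an estimated correlation). Muc16 fell from 145 ± 51.6 to 5.02 ± 3.76 CPM and Lgals7 from 110.4 ± 0.680 to 24.2 ± 13.7 CPM. In the immediate early and tissue handling list 8 of its 13 tested members rose and 1 fell (camera adjusted p = 0.0400, and adjusted p = 0.691 with an estimated correlation). Junb rose from 9.44 ± 3.07 to 43.4 ± 10.6 CPM and Nr4a1 from 17.6 ± 8.10 to 106 ± 44.7 CPM. In the list of mitochondrially encoded mRNA 9 of its 13 tested members rose and 0 fell (camera adjusted p = 0.0377, and adjusted p = 0.691 with an estimated correlation). mt-Co2 rose from 65.7 ± 32.3 to 448 ± 56.5 CPM. Day 8 replicate 1, in which mitochondrially encoded genes took 4.09% of reads, lay near the day 65 libraries in that share. Without day 65 replicate 3 Sohlh1 had 1 count against 4262, a ratio of 2406 with an exact binomial 95% counting interval of 432 to 95036, against a fitted fold of 615 with all libraries, and Muc16 was 47.1-fold lower in place of 28.1-fold.

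No call was made for the remaining lists. The Sertoli cell list had 3 members higher and 6 lower of 13 (camera adjusted p = 0.522). The corpus luteum list had 4 members higher and 3 lower of 10 (camera adjusted p = 0.485). The ovulation response list had 3 members higher and 5 lower of 10 (camera adjusted p = 0.518). The stromal fibroblast list had 5 members higher and 4 lower of 15 (camera adjusted p = 0.816). The smooth muscle and pericyte list had 6 members higher and 0 lower of 11 (camera adjusted p = 0.118). The endothelial list had 5 members higher and 3 lower of 13 (camera adjusted p = 0.439). The macrophage and antigen presentation list had 8 members higher and 1 lower of 15 (camera adjusted p = 0.0705). The lymphocyte list had 2 members higher and 2 lower of 5 (camera adjusted p = 0.515). The oviduct epithelium list had 0 members higher and 3 lower of 6 (camera adjusted p = 0.118). The adipocyte list had 1 member higher and 1 lower of 5 (camera adjusted p = 0.816). The erythroid list had 2 members higher and 0 lower of 6 (camera adjusted p = 0.267). The FOXO targets and PI3K feedback list had 3 members higher and 9 lower of 17 (camera adjusted p = 0.406). The TGF-beta family signalling list had 5 members higher and 9 lower of 24 (camera adjusted p = 0.518). The matrix remodelling and mesenchymal transition list had 7 members higher and 2 lower of 17 (camera adjusted p = 0.118). The interferon response list had 5 members higher and 2 lower of 11 (camera adjusted p = 0.268). Of members in these lists, Foxo1 rose from 88.3 ± 26.2 to 798 ± 115 CPM. Sesn1 fell from 61.8 ± 1.24 to 18.3 ± 5.48 CPM, Sesn3 from 147 ± 12 to 49.4 ± 8.91 CPM and Cdkn1b from 218 ± 14.9 to 78.03 ± 14.2 CPM. Timp1, a metalloproteinase inhibitor, rose from 22.2 ± 2.61 to 98.3 ± 12.6 CPM. The stromal fibroblast list had a median log2 fold change of -0.11 and a mean of -0.12, and camera's direction was up. The adipocyte list's median was -2.48 with or without bounds for members at 0. Adjusted over the list alone, passing members differed from the counts over all genes in granulosa cell (14 higher and 5 lower), erythroid (1 higher and 0 lower) and mitochondrially encoded mRNA (9 higher and 1 lower).

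Between day 65 and day 8, 11057 of 17747 genes differed by edgeR's quasi-likelihood test, 5267 higher and 5790 lower at day 65. With library size as the only scaling the share of higher genes was 34.8% in place of 47.6%, and the median of all genes moved by -0.28 on the log2 scale. Of the 10 lists called, none passed with an estimated correlation. There, 0 lists had an unadjusted p under 0.05 and the smallest adjusted p was 0.655. The fry test called 18. With the length and GC trend removed 1 list missed the threshold, with a median of the same sign, because its mean test statistic came closer to 0. The immediate early and tissue handling list had a median log2 fold change of 1.02 (quartiles 0.48 to 2.21) before and 0.95 (0.21 to 1.65) after (camera adjusted p = 0.118). With library size as the only scaling the camera adjusted p of the cell cycle list was 0.0815. Single libraries left out ended these camera calls, with the adjusted p in parentheses. The theca and steroidogenesis call ended without day 8 replicate 2 (0.0611) or day 8 replicate 3 (0.0548). The immediate early and tissue handling call ended without day 8 replicate 1 (0.0685), day 8 replicate 2 (0.0611) or day 65 replicate 2 (0.0807). The mitochondrially encoded mRNA call ended without day 8 replicate 2 (0.0737), day 8 replicate 3 (0.0676) or day 65 replicate 2 (0.0608).

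Calls at the step from day 8 to day 50 were set against those at the step from day 50 to day 65, which share the day 50 libraries. Scarb1, the high-density lipoprotein receptor gene, rose at both steps, from 106 ± 4.70 to 329.6 ± 31.5 CPM and then to 657 ± 114 CPM. Axin2 and Muc16 fell at both steps, Axin2 from 95.9 ± 23 to 37.6 ± 2.91 CPM and then to 3.94 ± 1.48 CPM, and Muc16 from 145 ± 51.6 to 34.8 ± 4.91 CPM and then to 5.02 ± 3.76 CPM, a step of 6.74-fold that was 11.4-fold without day 65 replicate 3. In all 767 genes rose at both steps and 778 fell at both, while 1417 rose and then fell and 1187 fell and then rose. Independent lists of the same sizes would share 951, 1076, 980 and 1044 genes in that order. Simulated unchanged groups gave at most 1 gene. As groups without a change yield few calls at either step, that count was largely fixed in advance and is no reference for these overlaps. The covariance of the log2 fold changes was -0.15, against -0.07 for simulated unchanged groups, a difference of -0.08. Their Pearson correlation across genes, which are not independent replicates, was -0.06 against -0.49 for simulated unchanged groups, and a difference of correlations does not estimate a shared effect. The simulated groups had 1 dispersion per gene for all ages. In the real libraries the biological coefficient of variation was 12.0% at day 50, 27.4% at day 8 and 28.0% at day 65. The covariance from sharing day 50 depends on the day 50 spread, so these simulated values and the difference of -0.08 do not measure it. The 3 day 50 libraries cannot be split into groups of at least 2, so part of the difference from the independent counts may come from sharing them. With library size as the only scaling 431 genes rose at both steps, and without day 8 replicate 3, or day 50 replicate 1, 2 or 3, there were 508, 409, 444 and 445 genes that fell at both.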

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

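The alternative that removes each library's trend on gene length and GC content was chosen after seeing the data, and the others were fixed beforehand. In the counts of called genes, 7249, 9916 and 11057 for day 50 against day 8, day 65 against day 50 and day 65 against day 8, each alternative apart from the fold threshold stayed within 1.5 times the main count. With a fold change of at least 2 the counts were 4351, 6003 and 7363, since that alternative adds a criterion. Leaving out 1 library gave 5524 to 8062, 8162 to 10931 and 9913 to 11823 genes. With only the 6 compared libraries in the fit, so that the third age did not enter the spread, the counts were 7884, 10114 and 9624. With the length and GC trend removed 8109, 8902 and 10934 genes passed. That alternative kept 67.8% of the calls between day 65 and day 50, with 122 genes called in the opposite direction, and 79.5% of those between day 65 and day 8, with 99 in the opposite direction. With library size as the only scaling, the share of higher genes was 35.5% between day 65 and day 50 and 34.8% between day 65 and day 8. The corresponding shares with TMM were 49.2% and 47.6%, and the median of all genes moved by -0.26 and -0.28 on the log2 scale.

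In the same order, camera called 16, 9 and 10 lists. With an estimated correlation it called 0, 0 and 0 lists, with 3, 1 and 0 lists at an unadjusted p under 0.05, and fry called 17, 15 and 18. Leaving out 1 library gave 12 to 17, 6 to 10 and 7 to 11 lists. The count of 9 became 6 without day 65 replicate 2. With the length and GC trend removed 11, 10 and 9 lists were called, among them the Sertoli cell, theca and steroidogenesis, and macrophage lists as lower at day 65 than at day 50.

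Genes rising at both steps numbered 767, against 431 with library size as the only scaling and 235 with a fold change of at least 2 at each step. Genes falling at both steps numbered 778, against 437 with that fold threshold. Leaving out 1 library gave 523 to 899 rising and 409 to 916 falling genes, with 508 falling without day 8 replicate 3 and 409, 444 and 445 without day 50 replicates 1, 2 and 3. With the length and GC trend removed 814 rose and 814 fell. The biological coefficient of variation ranged from 12.6% (without day 8 replicate 1) to 34.4% at day 8, from 10.4% to 12.9% at day 50 and from 22.7% to 30.5% at day 65 as single libraries were left out.

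As a replicate block, replicate number left 6735, 9368 and 10736 genes, 17, 10 and 11 lists, and 661 rising and 697 falling genes. The numbers do not appear to pair libraries across ages. Residual correlations between libraries of the same number ran from -0.0432 to 0.0520, and 1 of 9 libraries correlated best with a library of its own number.

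Named genes were run only under the 7 kinds of alternative whose losses are given here. Of 340 named pairs of a gene and a comparison, 336 were called, and 33 of the 340 lost their call or turned in at least 1 alternative. The other called pairs kept both their direction and their call wherever these alternatives gave them a value. The Wald test of DESeq2 gave none for Padi6 at day 65 against day 8 and Slc4a1 at day 50 against day 8. The losses involved 24 pairs when a library was left out, 18 with the length and GC trend removed, 14 with library size as the only scaling, 3 in the replicate block, 2 with the Wald test of DESeq2, 1 with DESeq2's size factors and 1 with the effective length offset. With the length and GC trend removed, 3 log2 fold changes turned: Egfl7 to -0.053 (edgeR adjusted p = 0.861) and Gadd45a to -0.11 (edgeR adjusted p = 0.716) at day 65 against day 50, and Pik3ca to 0.62 (edgeR adjusted p = 0.0194) at day 65 against day 8. The cause was not tested for these changes, apart from the criterion added by the fold threshold. Low counts limited recovery on simulated data: 41.9%, 41.5% and 45.3% of genes under 10 CPM with a 4-fold change were recovered. Those draws changed 200 of 17747 genes, with 1 dispersion per gene for all ages. The rates need not hold for the real libraries, where 7249 to 11057 genes were called and the spread differed between ages.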

Other observations

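Of the tests weighed here, those of day 8 replicate 1 against its age and of annotation differences between libraries, and the choice of gene families, came after the results were seen. Of 88 ribosomal protein genes, components of the ribosome, 84 rose and 0 fell between day 50 and day 65, with a median log2 fold change of 2.01 (0.89 and 71 risen with the length and GC trend removed). Between day 8 and day 50 54 of them fell and 0 rose, with a median of -1.10 (-0.69 with that trend removed). Of 47 respiratory complex I genes 39 rose and 1 fell between day 50 and day 65, with a median of 1.35 (0.25 with the trend removed, where 17 rose). Between day 8 and day 50 their median was -0.19 and turned to 0.14 with the trend removed. Of 40 proteasome genes 33 rose and 0 fell between day 50 and day 65, with a median of 0.94 (0.45 and 22 risen with the trend removed). Between day 8 and day 50 the proteasome median was -0.09 and turned to 0.01. Ribosomal protein genes also held 10.9% of reads in day 8 replicate 1, against 2.90% to 5.50% in the other libraries of day 8 and day 50.

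Hox genes, transcription factors of body patterning, rose in 15 of 29 members and fell in 2 between day 50 and day 65, with a median log2 fold change of 0.87 (0.64 with the length and GC trend removed, where 10 rose and 3 fell, and 0.61 with library size as the only scaling, where 8 rose and 3 fell). Protocadherin genes, which encode cell adhesion molecules, rose in 23 of 56 members and fell in 3 between day 8 and day 50, with a median of 0.97. Between day 50 and day 65 41 of them fell and 2 rose, with a median of -1.70 (-1.15 with the trend removed, where 27 fell and 5 rose). Of 382 genes with a Zfp symbol, which encode zinc finger proteins, 159 fell and 36 rose between day 50 and day 65, with a median of -0.45 (-0.11 with the trend removed, where 97 fell and 48 rose, and -0.71 with library size as the only scaling, where 212 fell and 18 rose).

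Longer genes were lower at day 65 than at day 50, with a Spearman rho of -0.401 across genes and 0.019 after each library's trend on length and GC content was removed. The short ribosomal protein, respiratory chain and mitochondrial genes as the whole source are argued against by a rho of -0.377 without these 387 genes. GC content as the whole source is argued against by a partial rho of -0.388 given GC content. A candidate explanation is a length bias of single libraries from RNA or library preparation: day 8 replicate 1 against replicates 2 and 3 of its age gave a rho of -0.364, so such a trend occurred within an age. As the 3 day 65 libraries each have a short mean effective length (1071 to 1195 bases), length bias and age stay confounded for the day 65 libraries, and a difference between the ages stays open and untested.

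Between day 65 and day 50, 472 genes differed at least 16-fold, 200 higher and 272 lower, of which 117 were at 0 in each day 65 library and 37 in each day 50 library. The correction for length and GC content moved genes by -2.19 to 0.97 on the log2 scale. After it 449 genes (95.1%) were still called in the same direction at 8-fold or more. The 272 lower genes met that fold in advance, as 0.97 was the largest upward move, and could lose only their call. A trend of that size is argued against as the whole cause for the 472 genes, since 16-fold is 4 on the log2 scale. A bias of another form was not tested. Reads shared with overlapping genes as the whole source are argued against by the 13.8% of these genes (65) with at least 50% of exon bases overlapped, against 2.89% of other genes, and those 65 stay open. An annotation that differed between the ages is argued against by the gene models of the 9 tables, in which the transcript names of each of the 472 genes were the same, 0 of the 237 with a single transcript differed in length, and effective length differed by at most 0.18 bases between libraries for each of 5090 single-transcript genes. A strand setting of the counting that differed between the ages stays open: of 292 genes overlapped on the opposite strand 36.0% differed at least 4-fold, between the bounds set for the test, against 29.0% of 269 overlapped on the same strand and 14.03% of other genes, and the age difference itself is untested.

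Of the 22 oocyte genes with a mean of at least 1 CPM at day 50, from day 50 to day 65 8 were lower and 3 higher, and 13 and 1 with the length and GC trend removed. A lower share of oocytes, with each oocyte unchanged, would move them alike, within 1.5 times their median standard error. The SD of their log2 fold changes was 2.38 times that error, and 2.43 times after the correction, both below the bound of 3 set for excluding the explanation. A lower share of oocytes, a length and GC bias and a change within oocytes with age therefore cannot be told apart for these genes. Whether a lower share of oocytes accounts for the falls of the oocyte list from day 8 to the later ages was not tested.

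The 6 libraries of a pair of ages make 10 splits, too few for a share under 0.05. For called genes the real splits gave 7249, 9916 and 11057 for day 50 against day 8, day 65 against day 50 and day 65 against day 8, the highest other split gave 0 in each, and 1 of 10 splits was as large as the real one. Every other split mixed both ages in each group, so the age difference entered the spread within groups and favoured a low gene count in advance. Each also kept an imbalance of ages, so these splits do not represent groups without a difference. For called lists the real splits gave 16, 9 and 10 and the highest other 16, 10 and 9, with 2, 4 and 1 of 10 splits as large. For genes moving 1 way at both steps, the 767 rising and 778 falling were reached by 1 of 60 drawn splits each, the real one, with 0 as the highest other. Only 2 of the 59 other splits called any gene at each step, so for the rest a count of 0 was fixed, and the splits do not tell whether chance accounts for these counts. Both counts lie below the 951 and 1076 of independent lists.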
